A study of Homo sapiens with 4 samples.

How the data were processed

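The screen used HK-2 cells, an established line of human renal proximal tubular epithelium, which carried Cas9 and a PRCC-TFE3 fusion gene switched on by doxycycline. Per the labels, the cells received the Brunello lentiviral library, a pool of sgRNAs that covers the protein-coding genes of the human genome, at a transduction efficiency of about 30%, with an average coverage above 500 cells per sgRNA. Puromycin at 5 µg/mL was applied for 7 days, the culture was divided on day 8 into a part with doxycycline (induced) and a part without (uninduced), and genomic DNA was taken from both on day 18. The procedure was carried out in 2 runs at different times, which the labels call independent biological replicates, so that there were 4 libraries, 2 per group and 1 of each group per run. No library of the plasmid pool or of cells before day 8 was used here.

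The deposited count table holds, for each library, whole-number read counts of sgRNA cassettes amplified by PCR from genomic DNA and sequenced on an Illumina instrument, per the labels. The counts were not normalized, which was checked from their differing totals. It lists 77441 sgRNAs, of which 1000 were non-targeting and 76441 were directed at 19114 genes, and 3 sgRNA names were carried by 2 rows each, which were kept as separate sgRNAs. The submitters' processing notes name MAGeCK and the build hg38, and the version of MAGeCK and its settings are not given in the sources used here. A deposited gene table with the column names of a MAGeCK gene summary gives, per gene and direction, a score, a p-value and FDR, a rank, the number of sgRNAs and a log2 fold change, per the file headers. That the deposited log2 fold change is induced over uninduced was checked against the counts. Across genes, it had a Spearman correlation of 0.952 with an unpaired median sgRNA log2 fold change and of 0.772 with the paired fit described below. Its number of sgRNAs equalled the sgRNAs with any count for 19058 of its 19062 genes and was never above 4, the number of sgRNAs of most genes in the library.

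Each sgRNA name in the count table carries a genomic position. Of 19114 gene symbols, 17852 were matched to a gene table of the GRCh38.p14 assembly (the same coordinates as hg38) by symbol and 1135 by an older symbol, and 127 were not matched. For matched genes, 99.92% of the positions lay inside the span of the named gene. Chromosomes and gene spans come from that table. Exons were not annotated here.

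Total counts per library were 9614976 (uninduced, run 1), 9902425 (induced, run 1), 11381147 (uninduced, run 2) and 9953674 (induced, run 2). The mean count per sgRNA was thus 124 to 147. PCR reads without molecular identifiers are not independent molecules, so counting floors cover counting error only. No fold is given against a library with no reads for any sgRNA of a gene, as 1 template can stand for many reads.

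sgRNAs with a mean count of at least 20 over the 4 libraries were tested for induced against uninduced with edgeR 4.0.16 in R 4.3.3 (TMM normalization, quasi-likelihood test, run as a block, 1 residual degree of freedom, 2-sided, Benjamini-Hochberg adjustment, threshold 0.05). The block was part of the main design because the series description states that each run was a pair. In the counts, the deviations of the 2 libraries of a run from their group means were nearly unrelated (correlation 0.0101 across sgRNAs), so the pairing rests on the description. Gene-level tests ranked the 1-sided edgeR p-values of sgRNAs and combined the ranks of a gene's sgRNAs by robust rank aggregation, the kind of gene test that MAGeCK uses. Only sgRNAs with p under 0.25 entered, the null came from 2000000 random sgRNA sets of equal number, genes needed at least 2 tested sgRNAs, and the 2 directions were adjusted separately. The effect size was the median log2 fold change of a gene's sgRNAs. All gene-level p-values below come from this edgeR-based test unless another source is named.

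As each sgRNA had its own read number, a scale-free level was also used. The relative level of a gene in a library is the mean count of its sgRNAs divided by the mean count of the sgRNAs against olfactory receptor genes in the same library. No sgRNA was left out of it. A change in relative level is given per run as the log2 ratio of induced to uninduced, and its mean with the SD over the 2 runs.

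A set of 30 gene lists was fixed before the data were examined and tested with camera in limma 3.58.1 on log2 CPM of sgRNAs (prior count 2, preset correlation 0.01, Benjamini-Hochberg over lists). The lists were the fusion partner genes, TFE3 relatives with the folliculin complex, mTORC1 with Rag GTPases and Ragulator, negative regulators of mTORC1, the p53 pathway, CDK inhibitors with the RB family, Mediator, SWI/SNF, SAGA and ATAC, CBP/p300 with BET and the super elongation complex, COMPASS, the PAF1 complex, NuA4/TIP60, Polycomb, HUSH, the m6A writer, the respiratory chain, the mitochondrial ribosome, the cytosolic ribosome, the proteasome, DNA replication, the spliceosome, the V-ATPase, autophagy, Hippo kinases, TGF-beta receptors and SMADs, growth suppressors, nuclear transport receptors, inflammatory senescence signalling and olfactory receptors. The cytosolic ribosome, the proteasome, DNA replication and the spliceosome together formed the core essential set of 190 genes and 760 sgRNAs. Markers of other cell types were not used, as the counts are of sgRNAs and not of transcripts.

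Genes were named by a rule fixed at the same time. It took TFE3 and PRCC, up to 12 genes per direction with the smallest gene-level p among those under adjusted p 0.05 with the same sign in both runs, the 2 members of each list with the smallest p in either direction, and the 10 genes ranked highest for enrichment in the authors' deposited table, 69 genes in all. Genes named outside this rule are marked as chosen after their values were seen.

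Alternatives chosen before the data were examined were a fit without the block, DESeq2 1.42.0 (its size factors and its Wald test), scaling to non-targeting sgRNAs, no count filter, a mean count of at least 100, each library left out (unpaired), counts summed per gene, a null from non-targeting sgRNAs, an adjusted p under 0.10, an estimated correlation for camera, and gene medians against 10000 random lists. Alternatives chosen after seeing the data were a fit on sgRNAs with reads in every library and the summed reads of a list against 10000 random lists matched on mean count in 10 classes, with 0.5 added to each side of the ratio. The relative levels and the intervals over genes or sgRNAs from 2000 bootstrap draws at the 95% level were also chosen after seeing the data. With an estimated correlation, camera rests on 1 residual degree of freedom, so hardly any list could pass, and its adjusted p cannot tell lists apart. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used for these steps.

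The tests were tried on simulated data with the means, library sizes and dispersions of these libraries, with 200 genes changed and 17251 genes tested. Each sgRNA had 1 mean share and 1 dispersion for all libraries. The simulation thus lacks the larger share of zeros of the uninduced library of run 2, and its recovery may not carry over. For induced against uninduced, 0 of 50 genes raised 4-fold and 0 of 50 lowered 4-fold were recovered at the threshold. At 16-fold, 2 of 50 raised and 6 of 50 lowered genes were recovered with the edgeR-based test, and 1 of 17056 unchanged genes was called. On the same simulated counts, camera in limma called a list of 20 genes raised 4-fold and did not call a list of 20 unchanged genes.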

Results

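The abundance of sgRNAs was measured in HK-2 cells on day 18, with or without expression of PRCC-TFE3 from day 8, a fusion oncoprotein of translocation renal cell carcinoma that joins part of PRCC to the transcription factor TFE3. According to the series description, the fusion drives these cells into senescence, and the comparison of induced with uninduced cells asks which gene knockouts let them escape it. There were 2 uninduced and 2 induced libraries, 1 of each per run, with 9614976 to 11381147 reads. None came from doxycycline-treated cells without the fusion gene, so effects of the drug and of the fusion cannot be told apart in any comparison below. The share of sgRNAs with no reads was 16.1% and 19.4% in the uninduced and induced libraries of run 1, and 42.1% and 20.8% in those of run 2. In the uninduced library of run 2, sgRNAs against olfactory receptors, used here as a reference, had no reads in 34.9% of cases, against 9.69% in the uninduced library of run 1. Non-targeting sgRNAs had 2.14 to 2.23 times the mean count of olfactory receptor sgRNAs in the 4 libraries. Whether this gap comes from the pool or from a cost of cutting cannot be read from these libraries, so relative levels hold for the olfactory receptor reference alone. Spearman correlations between libraries across sgRNAs, which are not independent replicates, ranged from 0.323 to 0.442.

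**Figure D1:**
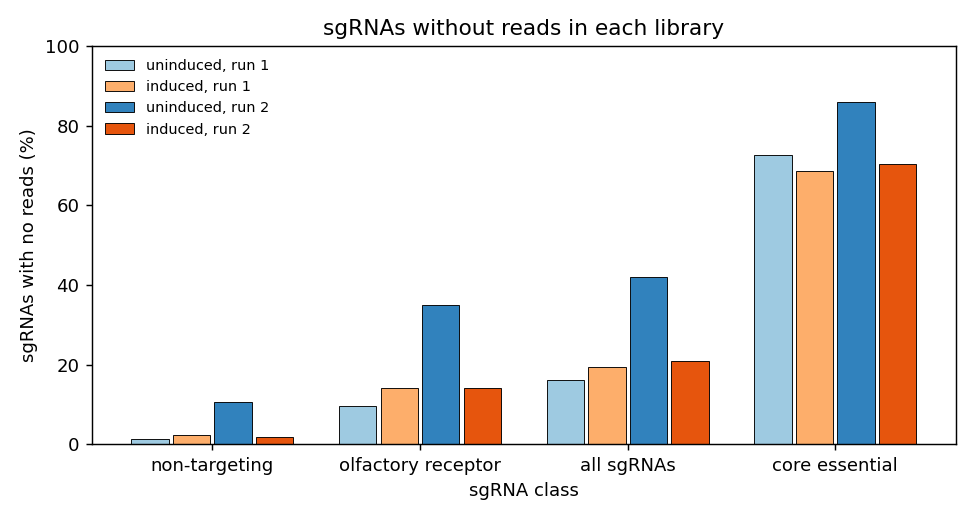
Share of sgRNAs with no reads (y axis, %) for non-targeting, olfactory receptor, all and core essential sgRNAs (x axis), with 1 bar per library. In the uninduced library of run 2 the share was the highest of the 4 libraries in each class, from 10.5% for non-targeting to 85.9% for core essential sgRNAs.

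TFE3 (chromosome X, 49028726 to 49043357, hg38) and PRCC (chromosome 1, 156767535 to 156800815), the genes joined in the fusion, were looked at first, because sgRNAs against either could also cut the transgene. Relative to olfactory receptor sgRNAs, the level of TFE3 sgRNAs was 0.68 uninduced and 1.01 induced in run 1, and 0.28 and 0.93 in run 2, a log2 change of 1.16 ± 0.82 (SD, n = 2 runs). PRCC sgRNAs had levels of 1.00 and 1.43 in run 1. In run 2 their level was 1.01 in the induced library, and no read was found in the uninduced library, where many sgRNAs had none. Of the 4 TFE3 sgRNAs, 2 were higher in induced cells in both runs, and the sgRNA at position 49034209 had 191 reads in the uninduced library of run 2 and 0 in the other libraries. Neither gene passed the edgeR-based test over all genes (adjusted p = 1 for both) or over the 2 genes alone (adjusted p = 0.137 for TFE3 and 0.111 for PRCC). Of the sgRNAs against the 2 genes, 87.5% had no reads in the uninduced library of run 2 and 12.5% in each of the other libraries. Which part of each gene is present in the transgene is not given in the sources used here. As a list, the fusion partner genes had an adjusted p of 0.193 by camera in limma, and 0.922 with an estimated correlation.

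ELOF1, a transcription elongation factor that also acts in transcription-coupled DNA repair, was the only gene past the threshold for enrichment in the main edgeR-based gene test. Its sgRNAs (chromosome 19, positions 11554038, 11554059, 11554253 and 11554301) had a relative level of 1.02 uninduced and 3.67 induced in run 1, and of 1.69 and 3.88 in run 2. The log2 change was 1.52 ± 0.45 (SD, n = 2 runs), and all 4 sgRNAs were higher in induced cells in both runs. The fitted median log2 fold change was 1.81, with an adjusted p of 0.00924 from the edgeR-based gene test. The median over all genes was 0.45, but 1.17 without the uninduced library of run 1 and 0.03 to 0.06 without any 1 of the other libraries. Of 18472 genes tested, ELOF1 alone passed for enrichment and 0 passed for depletion. On simulated counts, the same test called 1 of 17056 unchanged genes, so a single call can arise by chance. Among the 18472 genes, an unadjusted p under 0.05 was reached by 921 for enrichment and 935 for depletion, where 924 each would follow from chance. With a null from non-targeting sgRNAs these were 211 and 384, and ELOF1 still passed (adjusted p = 0.0369). The call for ELOF1 was lost in the fit without the run block (adjusted p = 0.774). It was also lost in the unpaired edgeR fits that left out the uninduced library of run 1 (0.766), the induced library of run 1 (0.584), the uninduced library of run 2 (0.712) or the induced library of run 2 (0.947). With the block, it was lost with the DESeq2 Wald test (0.403), with sgRNAs counted in every library (0.184), with counts summed per gene (0.949) and with a mean count of at least 100 (0.0583), and over all alternatives its log2 fold change was 1.47 to 1.95. Without the uninduced library of run 2, the library with the most zeros, 1 gene passed for enrichment, CHST4, which is named after its values were seen.

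CDKN1A, which encodes the CDK inhibitor p21, a main effector of senescence arrest, lay next to ELOF1. Its relative level was 1.14 uninduced and 3.98 induced in run 1, and 0.64 and 3.56 in run 2, a log2 change of 2.14 ± 0.48 (SD, n = 2 runs). All 4 sgRNAs (chromosome 6, between positions 36684145 and 36684278) were higher in induced cells in both runs, and the fitted median log2 fold change was 2.45. The adjusted p was 0.0508, just above the threshold, and it ranged from 0.00647 to 0.949 over the alternatives, 5 of which put CDKN1A past it. With the null from non-targeting sgRNAs it was 0.942. CDKN2A, which encodes the inhibitor p16, was already high in uninduced cells. Its relative level was 3.19 and 5.81 in run 1 and 2.84 and 7.62 in run 2, with all 4 sgRNAs higher in induced cells in both runs (log2 change 1.14 ± 0.39, adjusted p = 0.395). Among the 10 tested CDK inhibitors and RB family members, CDKN1A and CDKN2A passed when adjusted over the list alone (adjusted p = 5.5e-05 and 0.00205), and none passed over all genes. The RB family, looked at after the values were seen, did not go the same way. RBL2 and RBL1 had log2 changes of -1.41 ± 0.53 and -1.19 ± 0.52, with all 4 RBL2 sgRNAs lower in induced cells in both runs, and RB1 had -0.89 in run 1 and 1.24 in run 2. Among the 8 tested p53 pathway genes, CDKN1A passed adjusted over the list alone, and again none did over all genes. CHEK2, a DNA damage kinase, had relative levels of 1.93 and 0.79 in run 1 and of 2.01 and 1.14 in run 2. As whole lists, neither group passed camera (adjusted p = 0.865 for CDK inhibitors and RB family, 0.583 for the p53 pathway).

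In the Mediator complex, a transcription coactivator, 3 of 24 tested members were enriched when adjusted over the list alone, and 0 when adjusted over all genes. MED12 and CCNC belong to its kinase module. MED12 sgRNAs had a relative level of 0.79 and 2.62 in run 1 and of 0.99 and 3.23 in run 2, with all 4 sgRNAs higher in induced cells in both runs (log2 change 1.72 ± 0.02, adjusted p = 0.355). sgRNAs against CCNC, which encodes cyclin C (chromosome 6), were nearly missing from uninduced cells, with 17 reads in run 1 and 0 in run 2. In induced cells they had 840 and 397 reads (adjusted p = 0.395). MED24, named after its values were seen as the last of the 3, had relative levels of 0.12 and 0.81 in run 1 and of 0.22 and 1.78 in run 2 (adjusted p = 0.484). The kinase module was not tested as a list, and others of its members, looked at after the values were seen, differed in direction. Log2 changes were 0.47 ± 0.23 for MED13, -0.57 ± 1.12 for MED13L, -0.52 ± 0.60 for MED12L and -0.18 ± 0.23 for CDK19. MED1, likewise chosen after its values were seen, had -1.33 ± 0.69, with all 4 sgRNAs lower in induced cells in both runs. The list as a whole did not pass camera (adjusted p = 0.868), and its sgRNAs had no reads in 41.1% and 46.0% of cases in run 1 and in 61.3% and 41.9% in run 2.

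Some members of SAGA, a histone acetyltransferase coactivator, lay at the other end. SUPT20H, a subunit of its structural core, had the smallest p for depletion of all genes. Its relative level was 3.28 uninduced and 1.12 induced in run 1, and 3.49 and 0.49 in run 2 (log2 change -2.19 ± 0.90, SD, n = 2 runs, adjusted p = 0.0647, and 1 with the null from non-targeting sgRNAs). TADA1, of the same core, had levels of 2.35 and 0.96 in run 1 and of 3.06 and 0.76 in run 2, with all 4 sgRNAs lower in induced cells in both runs (log2 change -1.65 ± 0.50, adjusted p = 0.208). Of 22 tested SAGA and ATAC members, 5 were depleted when adjusted over the list alone and 0 over all genes. The other 3, named after their values were seen, were TADA2B, TAF5L and TAF6L, with log2 changes of -1.89 ± 1.20, -1.63 ± 0.73 and -3.43 ± 2.05. All 5 genes were picked for depletion in these same counts, which biases their levels. Intervals over sgRNAs also do not measure the spread between runs. The 20 sgRNAs of these 5 genes together had a relative level of 2.02 (95% bootstrap interval over sgRNAs 1.44 to 2.64) in uninduced and 0.669 (0.350 to 1.01) in induced cells of run 1. In run 2 the levels were 2.56 (1.88 to 3.32) and 0.588 (0.365 to 0.847). Not all members did this: 10 of the 22 had a median fold change below 0 in both runs and 7 had one above 0 in both, beside 15.6% and 31.1% of all genes. TADA3, ENY2 and KAT2B, chosen after their values were seen, had higher levels in induced cells, with 0.71 and 1.03, 0.32 and 0.81, and 0.51 and 0.86 in run 1, and 0.69 and 0.96, 0.51 and 0.72, and 0.13 and 0.29 in run 2.

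The SAGA and ATAC list had the smallest camera p of the 30 lists (limma p = 0.0072), which did not pass after adjustment (adjusted p = 0.182, and 0.922 with an estimated correlation). The log2 ratio of its summed reads, induced over uninduced and relative to olfactory receptors, was -0.50 in run 1 (95% bootstrap interval over genes -0.95 to 0.01) and -0.95 in run 2 (-1.48 to -0.31). Over the alternatives, the list passed camera with sgRNAs of a mean count of at least 100 (adjusted p = 0.000248) and with sgRNAs counted in every library (0.0112). Its fitted gene medians against random lists did not go the same way, with a median log2 fold change of 0.58 beside 0.45 for random lists (percentile 65.6, adjusted p = 0.794). By run, the median of its genes was -0.38 in run 1 and 0.09 in run 2, below the -0.06 and 0.61 of all genes.

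**Figure D2:**
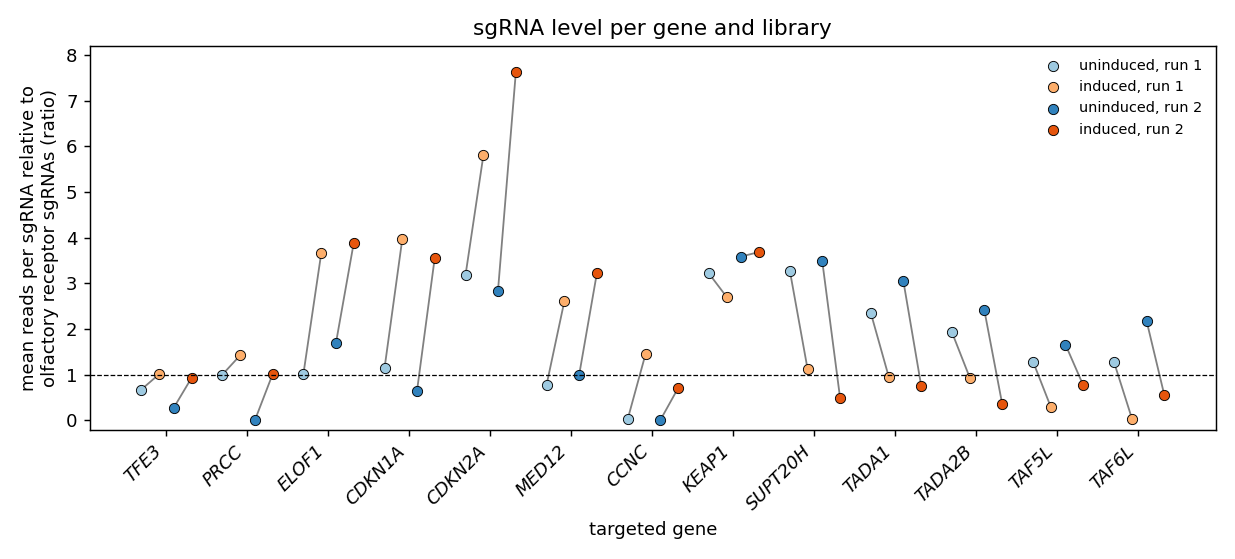
Mean reads per sgRNA of each gene divided by the mean of olfactory receptor sgRNAs in the same library (y axis, ratio) for selected genes (x axis). Each point is 1 library, lines join the uninduced and induced library of a run, and the dashed line marks the olfactory receptor level. ELOF1, CDKN1A, CDKN2A and MED12 had higher levels in both induced libraries, and SUPT20H, TADA1, TADA2B, TAF5L and TAF6L had lower ones, of which only ELOF1 passed the test over all genes.

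In further groups, 1 or 2 members passed when adjusted over the list alone and none over all genes. Here and above, adjustment over a list alone leaves the number of lists and directions uncounted, so some members can pass by chance. ARID2, a subunit of the PBAF form of SWI/SNF, had relative levels of 0.18 and 1.85 in run 1 and of 0.33 and 1.12 in run 2 (edgeR-based p adjusted over the list alone 0.0105, 1 of 26 members). AFF1, a scaffold of the super elongation complex, had 1.64 and 2.34 in run 1 and 0.41 and 2.71 in run 2 (0.0149 adjusted over the list alone, 1 of 16 members). RNF2, the Polycomb ubiquitin ligase, also passed adjusted over its list of 12 alone (0.0256), with a median log2 fold change of only 0.07, since 1 of its 4 sgRNAs was higher in induced cells in both runs and 2 were lower. KMT2A, of the COMPASS list, had levels of 0.21 and 1.16 in run 1 and of 0.30 and 1.11 in run 2 and did not pass (adjusted p = 0.885). METTL14, of the m6A writer list, had 1.24 and 0.13 in run 1 and 0.79 and 0.18 in run 2 (log2 change -2.71 ± 0.76, adjusted p = 0.894 for depletion). In the TGF-beta list, the receptors TGFBR2 and ACVR1B passed adjusted over the list alone (0.0470 and 0.0478). TGFBR2 had levels of 0.59 and 1.23 in run 1 and of 0.27 and 0.77 in run 2, and ACVR1B had 0.26 and 1.05 in run 1 and 0.97 and 1.05 in run 2.

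Lists of mitochondrial energy production did not pass camera, but both passed the test of summed reads against matched random lists, which was added after seeing the data (adjusted p = 0.0216 for both). Induced cells also had doxycycline, and an effect of the drug on these lists cannot be told apart from that of the fusion. For the 55 respiratory chain and ATP synthase genes, the log2 ratio of summed reads relative to olfactory receptors was 0.33 in run 1 (95% bootstrap interval 0.09 to 0.58) and 0.39 in run 2 (0.10 to 0.70). For the 77 genes of the mitochondrial ribosome the values were 0.36 (0.16 to 0.56) and 0.35 (0.13 to 0.57). The adjusted p by camera was 0.193 and 0.328, and 0.922 for both with an estimated correlation, and other lists such as the cytosolic ribosome (0.43 and 0.49) and NuA4/TIP60 (0.59 and 0.59) had log2 ratios as high. NDUFB6, a complex I subunit, passed adjusted over the list alone (0.0301), with levels of 0.36 and 1.40 in run 1 and of 0.26 and 1.13 in run 2. UQCRH, a subunit of complex III, went the other way, with 2.11 and 0.78 in run 1 and 2.24 and 1.65 in run 2 (adjusted p = 0.769 for depletion).

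By camera, 0 of the 30 lists passed, with adjusted p from 0.182 to 0.930, and 6 had an unadjusted p under 0.05. In 21 lists no member passed either adjusted over the list alone or over all genes, the 373 olfactory receptor genes included. Nutrient signalling to TFE3 was covered by 3 of them. Among TFE3 relatives and the folliculin complex, FNIP2 had levels of 1.81 and 2.34 in run 1 and of 0.88 and 1.54 in run 2. RRAGA, of the mTORC1 list, had 1.08 and 0.90 in run 1 and 1.34 and 0.32 in run 2. RRAGD, of the same list, went the other way, with 0.15 and 0.98 in run 1 and 0.27 and 0.90 in run 2. Of the 10 negative regulators of mTORC1, 6 had a median fold change above 0 in both runs and 0 had one below 0 in both, beside 31.1% and 15.6% of all genes, and the list did not pass camera (adjusted p = 0.182, and 0.922 with an estimated correlation). Among them, ITFG2 had levels of 0.86 and 1.34 in run 1 and of 0.21 and 0.82 in run 2, and DEPDC5 had 0.91 and 0.53 in run 1 and 1.78 and 1.56 in run 2. KEAP1, a growth suppressor that restrains the NRF2 stress response, was high in every library at 3.22 and 2.71 in run 1 and 3.59 and 3.69 in run 2. IPO5, an import receptor, had levels of 1.26 and 0.50 in run 1 and of 0.90 and 0.41 in run 2, with 3 of its 4 sgRNAs lower in induced cells in both runs (adjusted p = 0.985 for depletion). Mean log2 changes of these 21 lists, leaving out the pair of fusion partner genes, lay between -0.05 and 0.59 relative to olfactory receptors. The others among them were COMPASS, the PAF1 complex, NuA4/TIP60, HUSH, the m6A writer, the mitochondrial and cytosolic ribosomes, the proteasome, DNA replication, the spliceosome, the V-ATPase, autophagy, Hippo kinases and inflammatory senescence signalling.

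**Figure D3:**
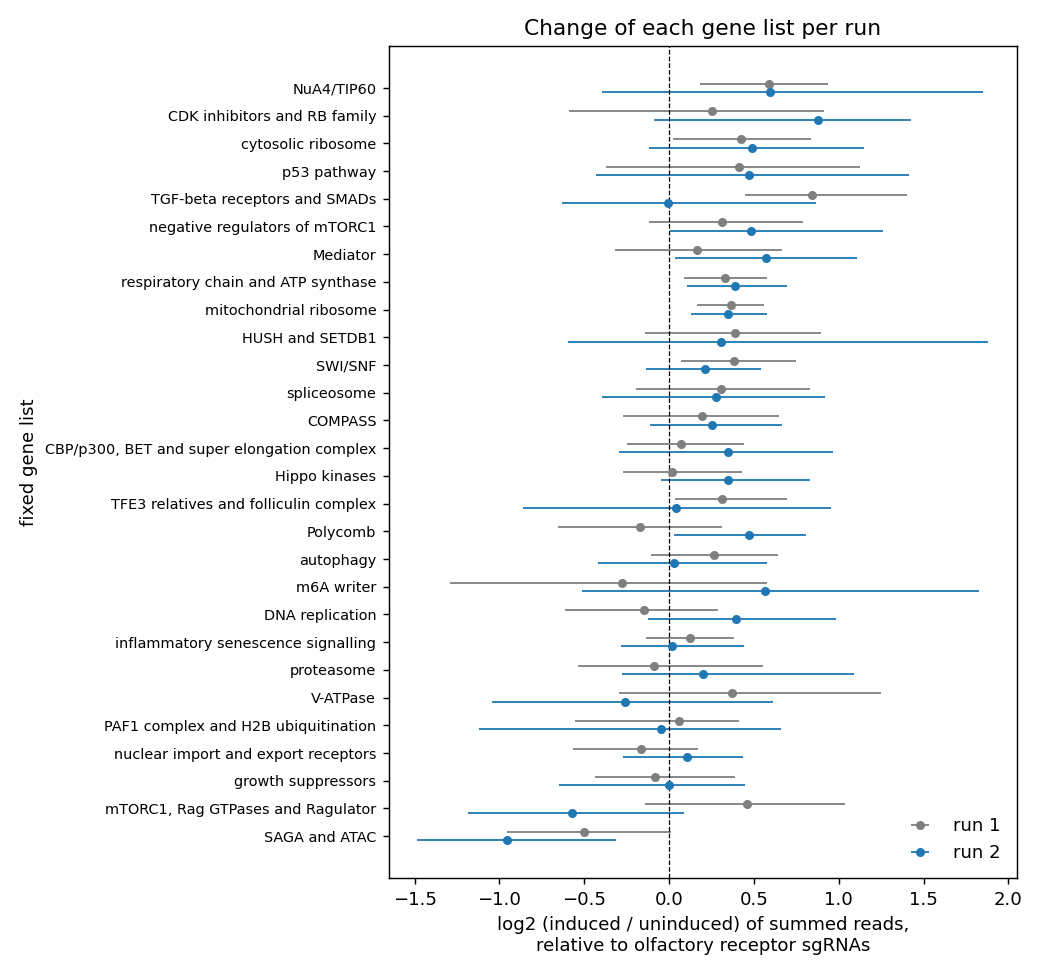
Change of the summed reads of each fixed list relative to olfactory receptor sgRNAs (x axis, log2 of induced over uninduced) in run 1 and run 2, with 95% bootstrap intervals over genes. SAGA and ATAC lay at -0.50 in run 1 and -0.95 in run 2. The fusion partner list, with 2 genes, is not drawn.

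sgRNAs against core essential genes were scarce in every library, with a mean count of 0.155 to 0.199 of that of olfactory receptor sgRNAs. With sgRNAs past the count filter, their median minus that of non-targeting sgRNAs was -2.85 and -2.71 (log2 CPM) in the uninduced and induced libraries of run 1 and -6.93 and -2.43 in those of run 2. The difference of induced from uninduced was thus 0.14 in run 1 and 4.50 in run 2 (mean 2.32 ± 3.08, SD, n = 2 runs), and without the count filter 2.21 and 3.71 (2.96 ± 1.06). Most of these sgRNAs had no reads in the uninduced library of run 2, so its median lies at the floor that the prior count sets, and the values of run 2 and those without the filter do not measure a change. In the uninduced library of run 2, 85.9% of core essential sgRNAs had no reads, against 68.6% to 72.6% in the other libraries. The log2 ratio of their summed reads relative to olfactory receptors was 0.17 in run 1 (95% bootstrap interval -0.06 to 0.41) and 0.36 in run 2 (0.05 to 0.68). RPL22 and RPS7 of the cytosolic ribosome had log2 changes in relative level of -2.11 ± 1.71 and -1.76 ± 0.38 and did not pass (adjusted p = 0.985 and 0.967 for depletion). The fitted median of RPS7, from 2 tested sgRNAs, had the opposite sign (0.96), and the summed reads of the whole cytosolic ribosome list lay higher in induced cells by 0.43 and 0.49 in the runs.

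At the level of single sgRNAs, 0 of 70176 were higher and 0 were lower at the threshold by edgeR. An unadjusted p under 0.05 was found for 192 higher and 95 lower sgRNAs (225 and 260 with non-targeting scaling). The 287 of the main fit are far fewer than chance alone would give. The edgeR test thus rarely calls an sgRNA, and its count of 0 does not show that sgRNAs were unchanged. The DESeq2 Wald test called 547 higher and 278 lower. The biological coefficient of variation was 158%. Across genes, which are not independent replicates, the fold changes of the 2 runs had a Spearman correlation of 0.0115 and a Pearson correlation of 0.0152. With sgRNAs of a mean count of at least 100 the Spearman correlation was 0.0438. The median fold change over all genes was -0.06 in run 1 and 0.61 in run 2 on the log2 scale, and that of non-targeting sgRNAs was -0.06 and 0.37.

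In the authors' deposited table, MYC was ranked highest for enrichment in induced cells, and BCL2L1, an inhibitor of apoptosis named after its values were seen, highest for depletion. The authors' deposited table has 0 genes under FDR 0.05 in either direction, and 1167 enriched and 1123 depleted genes with a p under 0.05. Its smallest FDR is 0.349 for enrichment and 0.0743, that of BCL2L1, for depletion. The sgRNAs against BCL2L1 had 189 and 459 reads in the uninduced libraries of runs 1 and 2. In the induced libraries they had 0, with 1 of the 4 sgRNAs lower in induced cells in both runs. No read of MYC sgRNAs was found in either uninduced library, against 165 reads in the induced library of run 1 and 382 in that of run 2. EIF6 (128 and 109 reads in the induced libraries of runs 1 and 2), COPE (157 and 166 reads) and NUP107 (273 and 171 reads), also among the 10 ranked highest in the authors' deposited table, likewise had no reads in uninduced cells. SYVN1, UBE3B and ZNF827 had relative levels of 0.74, 1.23 and 1.56 in the induced library of run 1 and of 0.66, 0.94 and 2.61 in that of run 2. Their levels in uninduced cells were 0.04, 0.27 and 0.94 in run 1 and 0, 0.37 and 0.15 in run 2. FBRSL1 and ZNF236 had levels of 0.31 and 0.97, and 0.12 and 1.08, in run 1, but differed little in run 2, with 1.04 and 1.41, and 0.73 and 0.88. ELOF1 and CDKN1A were ranked 2159 and 153 for enrichment in the authors' deposited table, and SUPT20H 383 for depletion. In the edgeR-based gene test, MYC had an unadjusted p of 0.182 for enrichment, from 3 tested sgRNAs. Of the 100 genes ranked highest, 18 for enrichment and 25 for depletion were also among the 100 smallest p of the paired test, which uses the same counts. EIF6 and COPE each had fewer than 2 sgRNAs with a mean count of at least 20 and were not tested here.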

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

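The fit on sgRNAs with reads in every library and the test of a list's summed reads were chosen after the data were seen. Without the replicate block, which the main design includes, 0 genes were enriched, and the numbers of depleted genes, lists and sgRNAs stayed at 0. Enriched genes numbered 2 with DESeq2 size factors, with non-targeting scaling and with no low-count filter (ELOF1 and CDKN1A each time). There were also 2 at an adjusted p under 0.10, and 1 with a mean count of at least 100 (CDKN1A, not ELOF1). With sgRNAs counted in every library there were 2, CDKN1A and RHAG, the latter named after its values were seen. The DESeq2 Wald test on sgRNAs and counts summed per gene gave 0. Unpaired fits without 1 library each gave 0 to 1 enriched genes, the 1 being CHST4, without the uninduced library of run 2. The lone library of a group was there assumed to vary like the others. Depleted genes numbered 1, SUPT20H, with non-targeting scaling, with no low-count filter and at an adjusted p under 0.10, and 0 in the other alternatives. With a null from non-targeting sgRNAs, 1 gene was enriched (ELOF1) and 0 were depleted, while CDKN1A moved to an adjusted p of 0.942 and SUPT20H to 1. In each run alone the sign of ELOF1 was kept. The median over all genes lay 0.14 lower on the log2 scale with non-targeting scaling. The median fold change of 0 to 10 of the named genes changed sign over 13 alternatives, none of them past the threshold.

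The DESeq2 Wald test called 547 higher and 278 lower sgRNAs, and each edgeR alternative called 0. Of the 30 lists, 1 passed camera with a mean count of at least 100 and 1 with sgRNAs counted in every library, SAGA and ATAC in both, a list that with an estimated correlation has an adjusted p of 0.922. Gene medians against random lists put 2 past the threshold, the cytosolic ribosome (up) and DNA replication (down). These random lists were not matched on count, and only 25 of 77 and 19 of 35 genes had enough tested sgRNAs to enter. The cytosolic ribosome median was -0.04 in run 1 and 2.74 in run 2, where 89.3% of its sgRNAs had no reads in the uninduced library. That of DNA replication was -1.06 and 0.19. Neither list passed camera (adjusted p = 0.583 and 0.790, and 0.922 for both with an estimated correlation). The summed reads of DNA replication had a mean log2 change of 0.12. Summed reads against matched random lists put 5, namely SAGA and ATAC (down), the fusion partner genes, CDK inhibitors with the RB family, the respiratory chain and the mitochondrial ribosome. None of these 5 passed camera (adjusted p 0.182 to 0.865, and 0.922 to 0.935 with an estimated correlation). With an estimated correlation all 30 lists lay at 0.922 to 0.935, on 1 residual degree of freedom, so that setting cannot decide. The fusion partner and CDK inhibitor lists lay at percentiles 99.8 and 99.9 in run 2 but at 81.8 and 81.0 in run 1. In 1 run alone, 11 lists had a sign opposite to that of camera. The correlation of the runs was 0.0438 with a mean count of at least 100. In the authors' deposited table, 1 gene was depleted at FDR under 0.10. The cause of these differences was not tested. In data simulated with the library sizes and dispersions of these libraries, 0 of 50 genes raised 4-fold were recovered.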

Other observations

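Of the tests below, those on Poisson sampling, on stronger loss, on the SAGA genes and on essential genes in general were chosen only after the results were seen. The tests on sgRNAs missing from the pool and on the number of near-absent genes were set before their values were known.

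A set of 12 genes had sgRNAs with reads in both induced libraries (relative level at least 0.25) and almost none in either uninduced library (at most 0.05), and these genes were singled out after their values were seen. They were ATP6V0D1, CCNC, CHMP5, COPE, DDX11, EIF3CL, MYC, NUP107, PPP1R8, RANGAP1, SMC3 and SYVN1. The opposite pattern, near absence from both induced libraries, held for 8 genes.

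These near-absent genes may reflect weaker selection against some knockouts in arrested cells, or chance sampling. A general relief of selection on essential genes would raise core essential sgRNAs, and the log2 rise of their summed reads against olfactory receptors was 0.171 in run 1 (95% bootstrap interval -0.06 to 0.41) and 0.359 in run 2 (0.05 to 0.68). Their mean level in induced cells was 0.176 (0.146 to 0.209) and 0.199 (0.162 to 0.245), which argues against a rise of essential genes in general to the level of 0.25 that defines the pattern, while a smaller rise or relief of single genes stays open. Sampling of few templates would make as many genes near absent from a mixed pair of libraries as the 12 of both uninduced libraries, and there were 8 for the induced of run 1 with the uninduced of run 2 and 4 for the induced of run 2 with the uninduced of run 1, a pair that lacks the library with the most zeros. With counts this small, sampling and relief of single genes cannot be told apart.

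The 42.1% of sgRNAs without reads in the uninduced library of run 2 could come from few templates per sgRNA, from a poorer pool or from stronger selection. If zeros come from a Poisson draw of templates, the ratio of -ln(share of zeros) of non-targeting to olfactory receptor sgRNAs should equal their ratio of mean counts. It was 2.17 (95% bootstrap interval 1.94 to 2.41) beside a ratio of mean counts of 2.13, among sgRNAs with reads in at least 1 library, and under this reading an olfactory receptor sgRNA had 1.08 templates on average there, against 2.04 to 2.48 in the other libraries. For non-targeting sgRNAs the zeros give 2.34 templates there and 4.41 to 5.80 elsewhere, but the variance of their counts gives 1.86 and 2.78 to 3.66, so the draw does not account for all of the spread and the numbers of templates are uncertain. They lie far below the average coverage above 500 cells per sgRNA that the labels give. In the other libraries too, the ratio of mean counts lay inside the interval, so this test does not set the uninduced library of run 2 apart. Nor can it tell at which step, in the cells or in the PCR, templates became few. A poorer pool as the sole cause is argued against by the olfactory receptor sgRNAs. Of the 522 missing from the uninduced library of run 2, 58.6% had reads in all 3 other libraries. Zeros were partly shared, however. Among all sgRNAs, 10296 had no reads in both libraries of run 2, against 6776 if zeros were independent, so a part of the pool stays open. Stronger selection is argued against by the rise of zeros from run 1, which was 25.2 percentage points for olfactory receptor sgRNAs and 26.0 for all sgRNAs.

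The low level of SAGA sgRNAs in induced cells, seen in summed reads but not in fitted gene medians (percentile 65.6 of random lists), is a candidate for follow-up. Sampling of the uninduced library of run 2 alone is argued against by run 1, where the list's change lay at percentile 0.08 of 10000 matched random lists. A growth gain from the loss of SUPT20H, TADA1, TADA2B, TAF5L and TAF6L in uninduced cells, or a disadvantage of it in induced cells, may underlie the difference, and the reading turns on the reference. Against olfactory receptors, the 5 genes lay at 2.02 (95% bootstrap interval 1.44 to 2.64) and 2.56 (1.88 to 3.32) in the uninduced libraries and at 0.669 (0.350 to 1.01) and 0.588 (0.365 to 0.847) in the induced ones, while non-targeting sgRNAs lay at 2.16 and 2.14 uninduced and at 2.20 and 2.23 induced, so that against these there is no gain beyond the intervals. The 5 genes were picked for this very difference, which biases the levels, and the readings cannot be told apart.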
